A study of Mus musculus with 2 samples.

How the data were processed

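DNase-seq, which sequences the ends of DNA that the nuclease DNase I cuts from open chromatin, was done on limb tissue of mouse embryos at embryonic day 10.5. The labels give 1 group with 2 biological replicates. They are separate biosamples of pooled male and female embryos that carry the same donor identifier. The labels do not say whether they came from different litters, so the spread between them may be partly technical. With 1 group of 2 libraries there is no contrast between conditions, and none was tested. Where the closing observations set the libraries against each other, percentiles and intervals describe these 2 libraries only. P-values below treat genes or regions as units and describe these libraries only.

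Per the labels, all coordinates are on mm10. The authors deposited, per library, 3 peak lists, 1 list of hotspots (wider accessible regions), 1 list of footprints (short protected stretches inside open chromatin) and false discovery rates per stretch of bases. Per the file headers and accompanying notes, the files derive from 2 filtered alignments of each library. The aligner, the peak caller and the footprint caller are not given in the sources used here. Replicates were called separately, so each library's list can be compared with the other's. The value of a peak in the main list is a signal in whole numbers that the authors deposited without naming its normalisation. It was used to describe, rank and filter peaks within a list. Ratios and rank correlations of values across the libraries are given as descriptions, since the values carry no stated common scale. The deposited score column of the peak and hotspot files was not used for a test. Hotspot values lie on a −log10 scale in the deposited files. The false discovery rate is a p-value type of measure, and the deposited files list only stretches under 0.05. The deposited footprint value is 0.01 in every line and ranks nothing. Signals in the longer list of the second alignment, as the authors deposited them, are multiples of 0.00432 in replicate 1 and 0.00356 in replicate 2. They are whole to within 0.05 of a step, and the scaling behind these steps is not stated. Read depth is not given in these files, and no count was inferred from the steps. The false discovery rates of the second alignment were not used here.

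The main peak list was chosen by a rule fixed before the data were examined: the newest processing, or, where several remain, the list with the most peaks. No list was dated, so the list with the most peaks was used in both libraries. Peaks of the 2 libraries that overlapped by 1 bp or more were joined into regions, and a region with a peak of both libraries is called shared. Chance overlap came from 100 circular shifts, within each chromosome for peaks and hotspots and within each hotspot for footprints. Intervals for shares of peaks are exact 95% binomial intervals, and intervals for genomic location come from 1000 bootstraps over blocks of 10 Mb. They cover counting error or local clustering, not the spread between embryos. Transcription start sites (TSSs) came from GENCODE vM21 and sequence from GRCm38, whose chromosome names and lengths fit the files. A promoter was the 1 kb on each side of a TSS: any annotated TSS for the location of regions, and the TSSs of a gene's coding transcripts for gene lists. Distal regions lay further away. The promoter value of a gene is that of the highest peak at any of its coding TSSs. That TSS need not be the one used in the cell type of the gene's list.

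Before the data were examined, 22 gene lists were fixed: limb mesenchyme, limb ectoderm, Shh, FGF, BMP, Wnt and retinoic acid signalling, chondrogenic, myogenic, endothelial, erythroid, macrophage, neural crest, neuronal, hepatocyte, cardiomyocyte, pluripotency and germ cell, olfactory receptor, housekeeping, anterior Hox, posterior Hox, and forelimb or hindlimb genes. The names Plzf and Ahsp matched no gene symbol. Each list was compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 22 lists and a threshold of 0.05. The measures were a promoter peak in both libraries, and membership of the top group of genes by number of shared distal regions within 100 kb of a coding TSS. The limit was set at the top 10%, and because of ties the group, with more than 12 regions, held 1746 of 21853 genes. Promoters were also compared with genes of equal CpG content (10 strata of observed over expected CpG) by 100000 permutations. Named genes were fixed by rule: every gene of a landmark list, the 2 members of each list with the highest promoter percentile, up to 2 members with no promoter peak in either library (first by alphabet), and the 10 genes with the most shared distal regions. Some genes that the rule takes are not reported here. Any other gene is said to have been chosen after its values were seen.

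Consensus sequences of 35 transcription factor motifs were searched on both strands within 75 bp of the centre of each shared distal region and in the flank 500 to 650 bp downstream. An exact two-sided sign test (McNemar) was made over regions, adjusted over the 35 motifs. Motif instances in peaks were set against footprints. Alternatives changed the peak list, the threshold on value, the overlap, the windows, the background or the replicate used.

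The scripts were tested on simulated data. Overlap code matched a base-by-base count in all 200 interval sets, with 0 that differed. Among simulated lists of 18 genes with a true promoter share of 0.15 against 0.65, 98.3% were called, against 1.5% of unchanged lists. Simulated lists drawn mostly from strata with a high share of peaks, and without a true difference, stood in for lists of CpG-rich genes. They were called in 68.2% of cases by the unmatched test and in 0% by the matched test. The power of the matched test to find a true difference was not simulated. All 4 planted motifs were recovered, and 0 of 31 others were called. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.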

Results

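Open chromatin was mapped by DNase-seq in limb tissue of mouse embryos at embryonic day 10.5, in 2 biological replicates. Limb buds at this age hold mesenchyme under an ectoderm, with vessels, blood, nerve and muscle precursors. The main lists held 104362 peaks in replicate 1 and 171128 in replicate 2, which is 1.64 times as many. Peaks covered 0.591% and 0.969% of the genome's bases. The question the design allows is which open regions both libraries share and which genes they lie at. Read depth is unknown, so a region without a peak is a region without a call.

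Replicate 1 had 74.998% of its peaks (95% interval 74.7 to 75.3) overlapped by a replicate 2 peak, and replicate 2 had 45.1% (44.9 to 45.4) overlapped by a replicate 1 peak. Shifted peaks gave 1.94% and 1.18%. Joined together, the peaks formed 195841 regions, of which 75850 were shared, 26093 had a peak in replicate 1 only and 93898 in replicate 2 only. Sharing rose with the deposited value, from 22.2% in the lowest 10% of replicate 1 peaks to 98.7% in the highest 10%, and from 1.05% to 98.2% in replicate 2. Of the regions with a peak in replicate 2 only, 11.7% held bases under a false discovery rate of 0.05 in replicate 1. In the other direction the share was 43.0%.

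**Figure D1:**
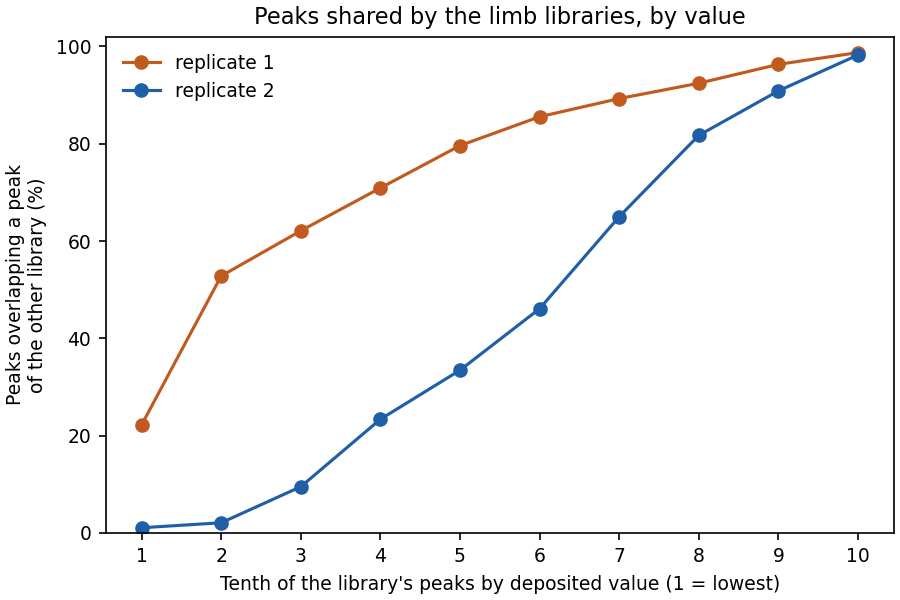
Share of each library's peaks (y axis, percent) that overlapped a peak of the other library, in 10 equal classes of the library's own peaks ranked by deposited value (x axis). The lines rise from 22.2% to 98.7% in replicate 1 and from 1.05% to 98.2% in replicate 2.

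Hotspots numbered 88615 and 140381, and their shared bases made up 50.8% of the union, against 0.957% after shifts. Across all regions, the rank correlation of the values was 0.535 (Spearman). For it, a region without a peak in a library took the lowest rank there. Of the 195841 regions, 26093 and 93898 had a peak in replicate 1 only and replicate 2 only, so 0.535 also reflects missing calls. Across shared regions, which by definition have a call in both libraries, the correlation was 0.932. Regions are not independent replicates, so no p is given. In shared regions the replicate 2 value was higher by a median of 0.76 on the log2 scale (interquartile range 0.47 to 1.02), and this difference was 0.42 in the lowest of 5 equal classes of regions by value and 0.94 in the highest. In the longer list of the second alignment the median was 0.50, with 0.16 in the lowest class and 0.70 in the highest. As the normalisation is not stated, this difference measures no change in accessibility. The X chromosome held 2.66% of replicate 1 peaks (interval 2.57 to 2.76) and 2.25% of replicate 2 peaks (2.18 to 2.32), with 6.18% of the bases. The Y chromosome held 55 and 60 peaks (0.0527% and 0.0351%), and the labels say that both sexes were pooled.

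Promoters held 37.9% of shared regions, 6.25-fold (6.08 to 6.44) their share of the genome. Exons held 4.37% (1.37-fold), introns 28.3% (0.735-fold) and intergenic sequence 29.5% (0.564-fold). Of regions seen in 1 library, promoters held 27.6% in replicate 1 and 16.2% in replicate 2. The promoter share of shared regions was 47.5% with a window of 2500 bp and 30.2% with 500 bp.

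All 39 limb mesenchyme genes had a promoter peak in both libraries, among them Snai1 (values 883 in replicate 1 and 1523 in replicate 2) and Msx1 (685 and 1212), a homeobox gene of distal mesenchyme. The same was true of all 14 Shh pathway genes (Gas1 739 and 1097, Sufu 711 and 1051), all 19 BMP genes (Smad6 746 and 1562), all 18 Wnt genes (Nkd1 925 and 1981, Fzd1 831 and 1280), all 14 retinoic acid genes (Rxrb 997 and 1942, Rarg 651 and 1223) and all 26 housekeeping genes (Actb 857 and 1803, Polr2a 835 and 1786). Limb ectoderm genes had 26 of 29, with Dlx2 at 468 and 992, Dlx6 at 440 and 1000, and no peak at Fgf17 or Krt14. Of the blood, macrophage, liver and olfactory lists, 4 of 18 erythroid genes (Nfe2 263 and 547, Tal1 267 and 419), 3 of 18 macrophage genes (Fcgr3 543 and 951, Coro1a 168 and 404), 3 of 18 hepatocyte genes (Foxa3 693 and 1131, Apoh 469 and 985) and 9 of 1091 olfactory receptor genes (Olfr94 209 and 458, Olfr464 150 and 563) had one. The erythroid genes Alas2 and Epb42, the macrophage genes Adgre1 and Aif1, the hepatocyte genes Alb, Afp and Ahsg and the receptors Olfr1 and Olfr10 had none in either library.

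Across 21853 protein-coding genes, 14560 (66.6%) had a promoter peak in both libraries. By two-sided Fisher's exact test, adjusted over 22 lists, the share was higher for limb mesenchyme (adjusted p = 1.78e-06), limb ectoderm (0.0179), Shh (0.0164), BMP (0.00228), Wnt (0.00228), retinoic acid (0.0164) and housekeeping genes (0.000143). It was lower for erythroid (0.000536), macrophage (0.000103), hepatocyte (0.000103) and olfactory receptor genes, whose p was below the smallest number the software holds. No other list passed Fisher's exact test: FGF 15 of 16 (Spry4 740 and 1937, Dusp6 790 and 1267), chondrogenic 15 of 18 (Col11a1 500 and 711, none at Matn1 or Snorc), myogenic 13 of 18 (Six4 484 and 734, none at Acta1 or Chrna1) and endothelial genes 11 of 18 (Fli1 694 and 1438, Egfl7 397 and 851, none at Cdh5 or Pecam1). Nor did neural crest genes with 10 of 14 (Mitf 446 and 712, none at Cdh19), neuronal 16 of 18 (Elavl4 540 and 1161, Snap25 396 and 961), cardiomyocyte 8 of 16 (Myl4 1005 and 1690, Hcn4 353 and 520, none at Myh6 or Myh7) or pluripotency and germ cell genes with 7 of 16 (Dazl 428 and 900, Esrrb 155 and 287, none at Dppa4 or Dppa5a). Anterior Hox genes had 20 of 23 (Fisher's exact test, adjusted p = 0.0737; Hoxa7 725 and 1406, Hoxa5 628 and 1257), posterior Hox genes 12 of 16 (adjusted p = 0.685; Hoxc10 644 and 1626, Hoxa10 572 and 1223) and forelimb or hindlimb genes 9 of 10 (Hoxc5 504 and 686).

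Promoter peaks followed CpG content: 1.37% of genes in the lowest 10% by observed over expected CpG had one, and 99.5% in the highest 10%. Against genes of equal CpG content, 0 lists were higher after adjustment over the 22 lists. For limb mesenchyme, Shh, BMP, Wnt and housekeeping genes this test could not give a higher call. All of their members had a peak, and the expected counts lay close to that limit. Retinoic acid genes alone were higher at an unadjusted p under 0.05, with 14 against 11.6 expected (two-sided permutation test, p = 0.0105, adjusted p = 0.0575). All 14 had a peak, the most the list can show, so a higher call was out of reach for it too. Limb mesenchyme genes had 39 against 37.1 expected (permutation test, adjusted p = 0.7), and the lower calls of erythroid genes (4 against 4.03), macrophage genes (3 against 4.22) and hepatocyte genes (3 against 6.23) ended as well. Pluripotency and germ cell genes were lower, with 7 against 13.3 expected (permutation test, adjusted p = 0.00022, from a p of 2e-05, the smallest the permutations can give; 9 against 13.8 and adjusted p = 0.0145 in replicate 2 alone), and so were olfactory receptor genes, with 9 against 92.4 (permutation test, adjusted p = 0.00022).

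Posterior Hox genes were also lower against equal CpG, with 12 against 15.2 expected (permutation test, adjusted p = 0.0324), and this call rests on replicate 1. In replicate 1 alone the count was 12 against 15.2 (permutation test, adjusted p = 0.0268). In replicate 2 alone all 16 had a promoter peak, against 15.4 expected (permutation test, adjusted p = 1). The 4 genes without a replicate 1 peak within 1 kb of a coding TSS, chosen after their values were seen, were Hoxa11, Hoxb9, Hoxc12 and Hoxd12, with replicate 2 values of 405, 330, 329 and 405. The anterior genes Hoxb3, Hoxc6 and Hoxd4, also chosen after their values were seen, had 337, 223 and 308 in replicate 2 and none in replicate 1. Of 12614 genes with a replicate 2 promoter value above 300, 11 had no replicate 1 peak, and 6 of these 11 were Hox genes. Without matching, replicate 2 alone gave 11 lists above other genes in place of 7, the further 4 being FGF (adjusted p = 0.0461), neuronal (18 of 18, 0.00421), anterior Hox (23 of 23, 0.00131) and posterior Hox genes (16 of 16, Fisher's exact test, 0.00871).

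The Hox clusters were among the regions most dense in shared peaks. HoxA (chromosome 6, 52155590 to 52260880) held 59, HoxB (chromosome 11, 96194316 to 96368256) 51, HoxC (chromosome 15, 102921103 to 103036852) 41 and HoxD (chromosome 2, 74668310 to 74765142) 56. They reached percentiles of 100, 99.98, 99.99 and 99.99 among 10000 random windows of equal length that held a TSS. A further 70, 84, 55 and 88 regions had a peak in replicate 2 only, and 17, 12, 27 and 17 in replicate 1 only. In the clusters and within 25 kb of them, 128 of 348 replicate 2 regions in the top 30% by value (36.8%) had no base under a false discovery rate of 0.05 in replicate 1.

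**Figure D2:**
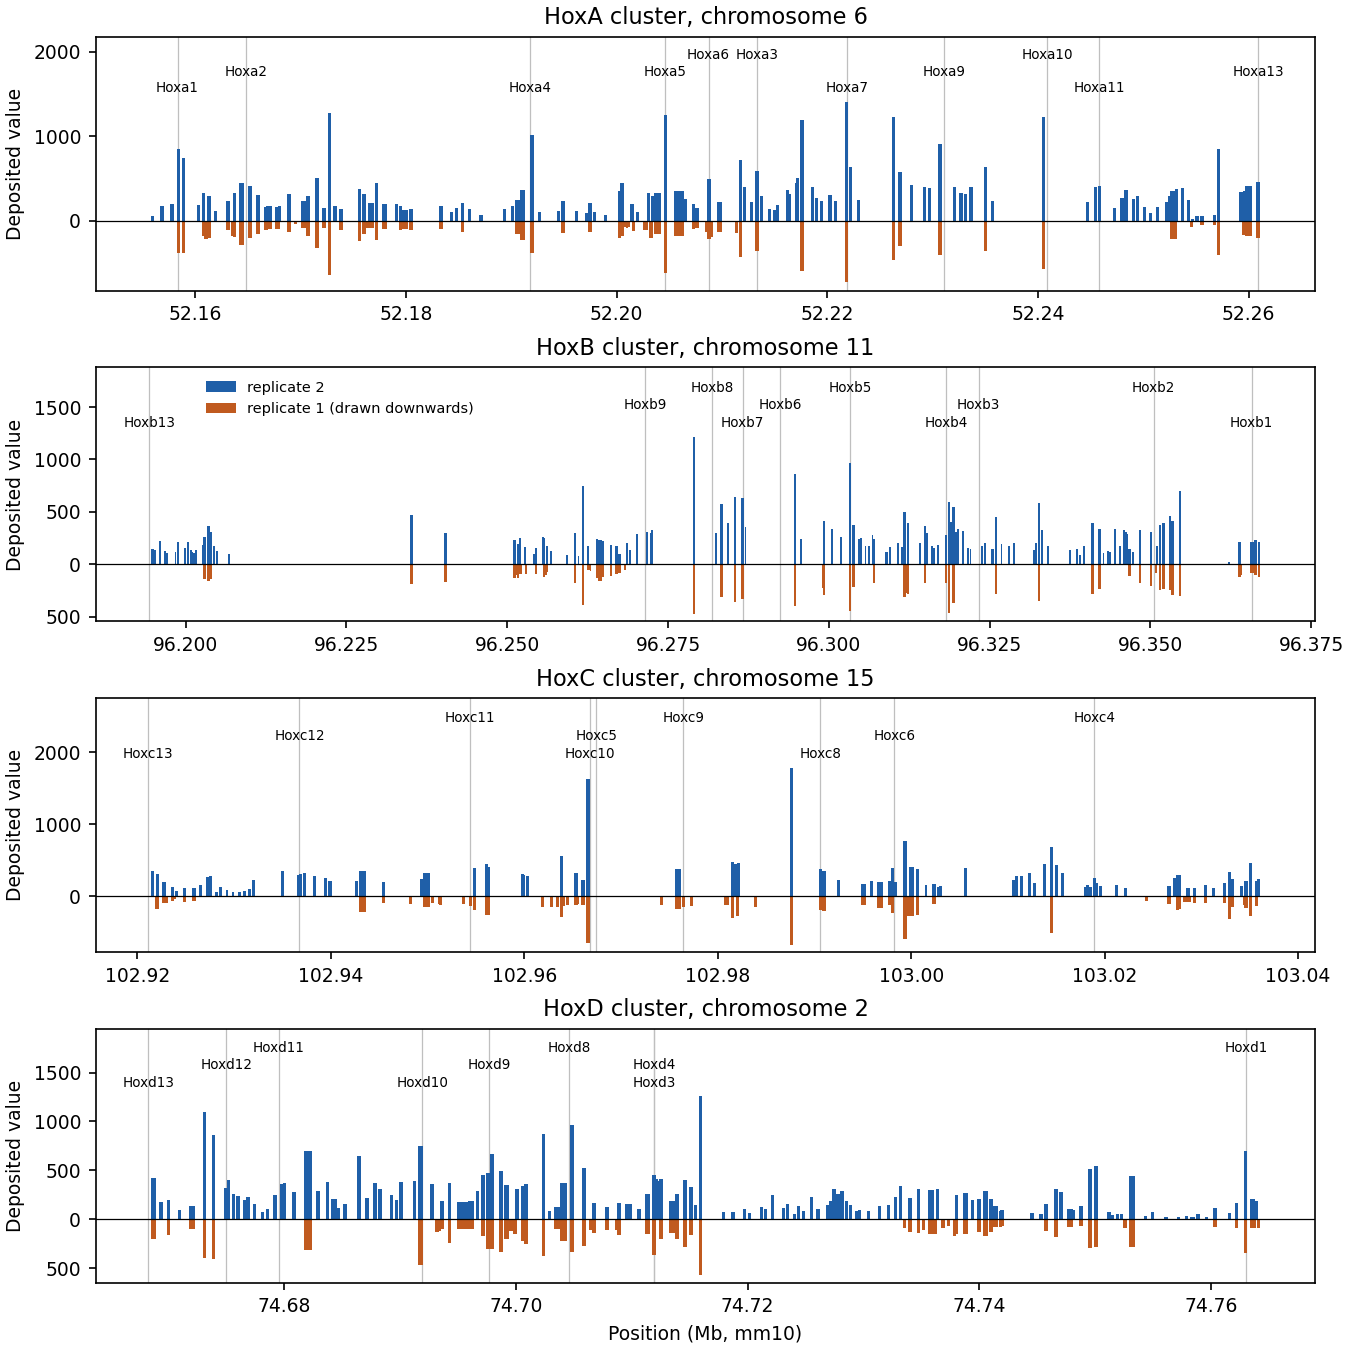
Deposited peak values (y axis) over the HoxA, HoxB, HoxC and HoxD clusters by position (x axis, Mb on mm10), with replicate 2 drawn upwards and replicate 1 downwards; bars are wider than the regions so that they can be seen, and grey lines mark the 5′ end of each gene record, which can lie away from the coding TSS. Stretches of replicate 2 peaks without replicate 1 peaks lie at Hoxa11, Hoxb9, Hoxc12 and Hoxd12.

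Of 47139 shared distal regions, a gene had a median of 4 within 100 kb, and the 1746 genes with more than 12 formed the top group, which held 7.89% to 8.36% of the other genes that each list was compared with. It held 20 of 39 limb mesenchyme genes, among them Lmx1b (43 regions), the dorsal determinant of the limb, Tbx2 (39), Tbx4 (38) and the forelimb gene Tbx5 (32). It also held 13 of 29 limb ectoderm genes, among them En1 (24) and Fgf8 (16), the growth factor of the apical ridge, 9 of 19 BMP genes, 7 of 18 Wnt genes, 5 of 14 retinoic acid genes, 6 of 18 chondrogenic genes including Sox9 (15), 5 of 16 FGF genes, 4 of 14 Shh genes, 5 of 18 myogenic genes, 5 of 14 neural crest genes, 8 of 10 forelimb or hindlimb genes, and all 23 anterior and all 16 posterior Hox genes. Hepatocyte genes had 0 of 18, and 11 of 1091 olfactory receptor genes reached it.

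By two-sided Fisher's exact test these lists were higher than other genes: limb mesenchyme (adjusted p = 8.72e-12), limb ectoderm (3.81e-07), BMP (1.80e-05), Wnt (0.000817), retinoic acid (0.00702), chondrogenic (0.00505), FGF (0.0123), Shh (0.0311), myogenic (0.0181), neural crest (0.00702), forelimb or hindlimb (2.80e-07), anterior Hox (5.51e-25) and posterior Hox genes (1.90e-17). Macrophage genes were higher too, with 5 of 18 (Fisher's exact test, adjusted p = 0.0181); C1qa, C1qb and C1qc, which lie side by side, were 3 of these 5, chosen after their values were seen. Olfactory receptor genes were lower (3.62e-25). Endothelial (3 of 18), erythroid (2 of 18), neuronal (2 of 18), hepatocyte, cardiomyocyte (2 of 16), pluripotency and germ cell (2 of 16) and housekeeping genes (2 of 26) did not pass. Neighbouring genes share regions, so members are not independent. With regions over 5 kb from a TSS the share of anterior Hox genes was 21.7% (Fisher's exact test, adjusted p = 0.057) and of posterior Hox genes 37.5% (0.00396), and forelimb or hindlimb genes without Hox genes had 50% (0.0508). In replicate 2 alone the calls of FGF (0.304), retinoic acid (0.0726), chondrogenic (0.48) and macrophage genes (0.731) ended. The call of Shh genes was kept in 4 of its 10 alternatives and lost in 6, one of them replicate 1 alone (Fisher's exact test, adjusted p = 0.19). Neuronal genes had 27.8% in the top group in replicate 1 alone (adjusted p = 0.0338) and 27.8% in replicate 2 alone (0.0499), and endothelial genes 27.8% in replicate 1 alone (0.0338) and 5.56% in replicate 2 alone (Fisher's exact test, adjusted p = 1). A window of 250 kb or the shorter list of the second alignment left 8 of the 14 lists higher.

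The genes with the most shared distal regions were Gse1 (57), Bcas3 (51), Btn2a2 (48), Auts2 (45), Lrmda (44), Lmx1b (43), Btn1a1 (42), Mecom (42), Tbx2 (39) and Mid1 (38), which ties with Tbx4 (38). Genes with several coding TSSs have wider windows: with 1 TSS per gene, an alternative chosen after the data were seen, Gse1 had 25, Bcas3 10, Auts2 4, Lrmda 29, Mecom 17 and Mid1 0. Btn2a2 (48), Lmx1b (43), Btn1a1 (42) and Tbx2 (39) had the same number and Tbx4 had 36. Bcas3 neighbours Tbx2 and Tbx4 on chromosome 11.

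**Figure D3:**
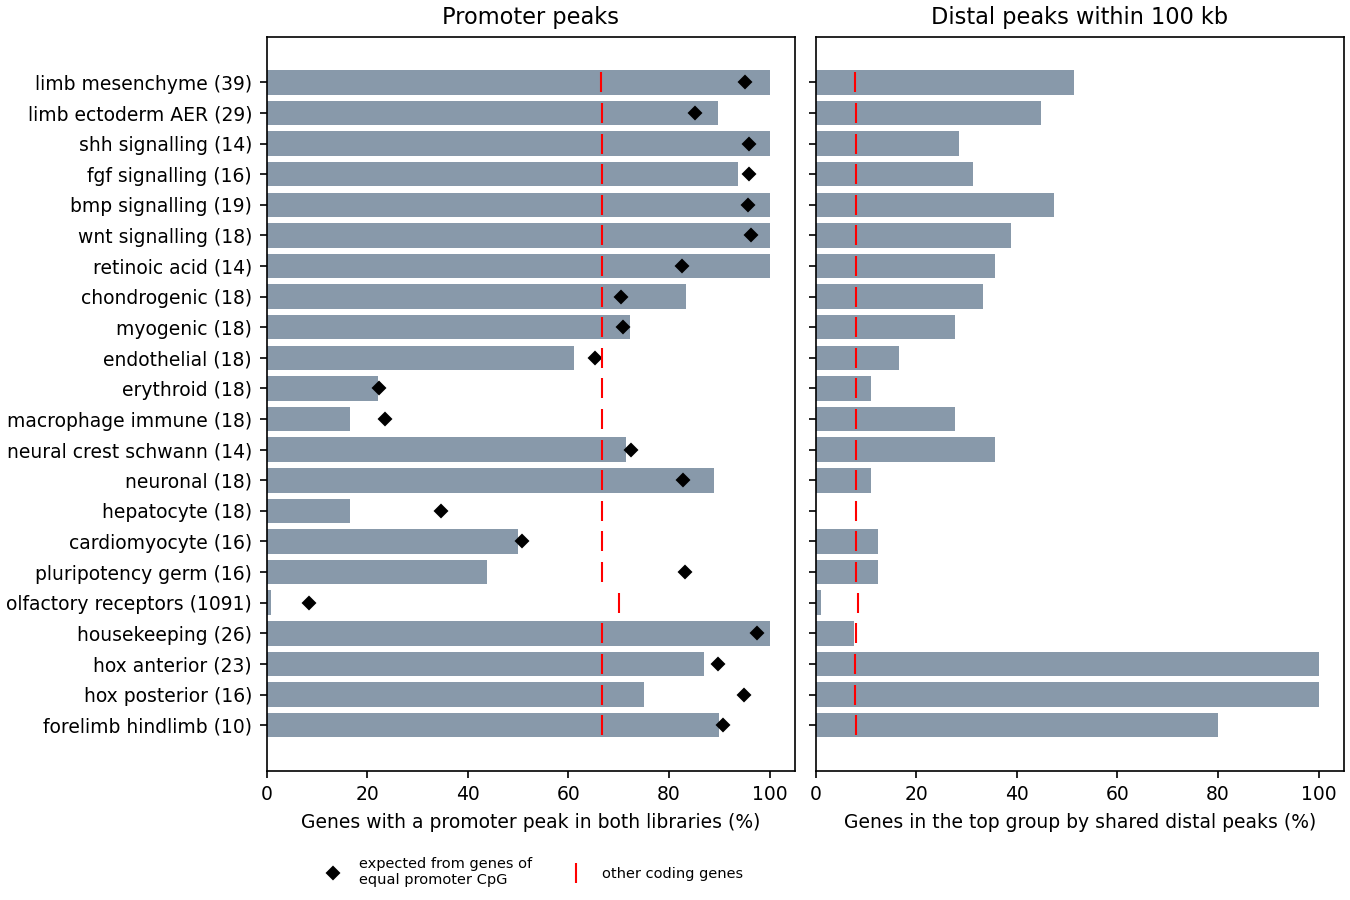
For each gene list (number of genes in parentheses), bars give the percent of genes with a promoter peak in both libraries (left x axis) and in the top group by shared distal regions within 100 kb (right x axis); red ticks are all other coding genes and diamonds the share expected from genes of equal promoter CpG. All 39 limb mesenchyme genes had a promoter peak, and 20 of 39 were in the top group.

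Landmark genes of limb patterning were open in both libraries at levels that differed between genes. Shh, the signal of the posterior limb margin (chromosome 5, 28456815 to 28467256), had promoter values of 98 and 187, the 41.2 and 69.1 percentiles of the libraries' peaks. Its pathway genes lay higher: Gli3 533 and 878, Gli1 475 and 978, Ptch1 588 and 834. Lmbr1, in whose intron 5 the limb enhancer of Shh is known to lie, had a promoter at 576 and 1161, and 3 shared regions in that intron (of the longest coding transcript, with 17 exons) at 29293322 to 29293485 (94 and 340), 29314676 to 29314845 (97 and 139) and 29314972 to 29315125 (90 and 86). These 3 were chosen after their values were seen. Proximal genes Meis1 (570 and 826) and Meis2 (383 and 705), the mesenchyme genes Prrx1 (364 and 412), Hand2 (344 and 544), Msx2 (509 and 829), Sall4 (389 and 644) and Irx3 (398 and 693), and the dorsal and ventral genes Lmx1b (448 and 812), Wnt7a (207 and 475) and En1 (308 and 536) had promoter peaks. So did the signals Fgf10 (340 and 521), Fgf8 (162 and 313), Bmp4 (353 and 531) and Grem1 (225 and 434), and the forelimb gene Tbx5 (228 and 411) beside the hindlimb genes Tbx4 (184 and 280) and Pitx1 (219 and 379). Hoxd13 (216 and 426), Hoxa13 (203 and 455), Hoxd11 (311 and 699), Sox9 (462 and 664) and the muscle gene Myod1 (208 and 276) were open too. Alb, the serum albumin gene of liver, had no promoter peak and 1 shared region in exon 7 (120 and 206).

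The motifs with the highest fold at the centres of shared distal regions were those of REST and CTCF. The site of the insulator protein CTCF was found in 9.30% of centres and 0.172% of flanks (54.1-fold), and the REST site in 204 centres and 1 flank. The MyoD-type E-box was in 9.65% against 3.40% (2.84-fold). Against flanks, which had lower GC content, SP and KLF sites were 3.08-fold, NRF1 3.43-fold, ETS 2.68-fold, CREB 2.46-fold and TFAP2 2.06-fold more frequent. Sites of GLI, the Shh effectors, were 2.29-fold more frequent. Smaller rises were seen for NF-Y (1.47-fold), TCF and LEF (1.44), HOX-PBX (1.39), SOX (1.31), TEAD (1.31) and TWIST-type E-boxes (1.24), and the PU.1 site was in 10 centres and 1 flank. Lower at the centre were GATA (0.508-fold), posterior HOX (0.464), PITX (0.482), LIM homeodomain (0.798), forkhead (0.833) and octamer motifs (0.803).

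These 16 higher and 6 lower motifs passed the exact two-sided sign test over 47139 regions, adjusted over 35 motifs, with the largest adjusted p at 0.0186 (PU.1 site). RUNX, SRF and MEF2 motifs did not pass against the flank. They were higher against shuffled sequence (1.68, 2.05 and 4.06-fold) and at equal GC and CpG (1.34, 1.79 and 1.57-fold, exact sign test, adjusted p at most 0.0358 in both). Directions of several AT-rich motifs differed between backgrounds. Centres had 53.5% GC and flanks 46.1%. Fold sizes depended on the background too. At equal GC and CpG, SP and KLF (1.25-fold), GLI (1.56), TFAP2 (1.52) and MyoD-type E-box sites (1.85) had smaller folds than against the flank. So did NRF1, CTCF (31.99), REST (40.8) and NF-Y sites (1.41). HOX-PBX (3.18), SOX (1.71), TEAD (1.62), TCF and LEF (1.53) and TWIST-type sites (1.39) had larger ones. Shuffled sequence gave 7.39-fold for SP and KLF and 1.41-fold for GLI sites. Against shuffled sequence and windows of equal GC and CpG, LIM homeodomain (3.20-fold and 2.12-fold), forkhead (1.89 and 1.34) and octamer motifs (1.66 and 1.27) were higher at the centre, posterior HOX was 1.31 and 0.879 and PITX 1.14 and 0.424, while GATA stayed lower (0.726 and 0.674). At equal GC and CpG, ETS (1.21-fold, adjusted p = 0.312) and CREB (1.302-fold, adjusted p = 0.0658) no longer passed the exact sign test, nor did NF-Y (1.04-fold, adjusted p = 0.534) and TFAP2 (1.09-fold, adjusted p = 0.413) against shuffled sequence. HOX-PBX was 0.899-fold in replicate 2 alone (exact sign test, adjusted p = 0.0248), the opposite direction. The PU.1 site passed in 2 of its 8 alternatives. TEAD (adjusted p = 0.253), GLI (0.0547) and TCF and LEF sites (0.0503) did not pass the exact sign test in the shorter list of the second alignment. Of 10 alternatives, the octamer call was kept in 5, lost in 3 and reversed in 2, and the LIM homeodomain call was kept in 7, lost in 1 and reversed in 2.

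**Figure D4:**
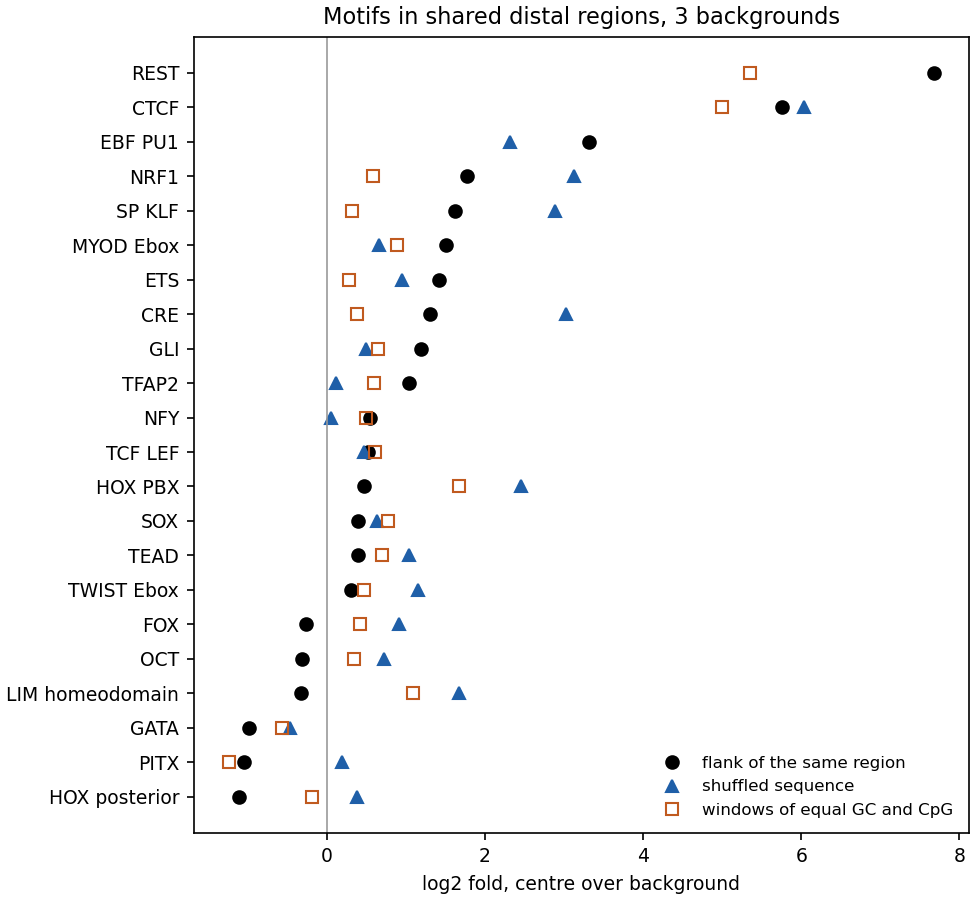
Log2 fold (x axis) of the share of shared distal regions with each motif at the centre over 3 backgrounds, for the 22 motifs that passed the test against the flank (y axis). CTCF and REST lie far to the right, and LIM homeodomain, forkhead and octamer motifs change side with the background.

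Footprints numbered 252786 in replicate 1 and 377894 in replicate 2, with a median width of 9 bp. Of these, 48.4% and 31.4% overlapped one of the other library. The shares were 14.5% and 10.9% after the other library's footprints were rotated within each hotspot by up to 1 kb. No rotation exceeded the width of its hotspot, with medians of 268 and 259 bp. Footprints not wholly inside a hotspot were left out of the rotated sets. REST sites in peaks lay in footprints in 85.1% and 94.9% of instances (replicates 1 and 2), CTCF sites in 83.4% and 90.9%, NRF1 in 82.1% and 81.1%, CREB in 66.8% and 64.3%, ETS in 61.8% and 63.8%, and SP and KLF in 58.8% and 61.0%. Footprints covered 12.3% and 10.96% of peak bases. GLI sites (22.2% and 27.2%) and the MyoD-type E-box (19.3% and 20.04%) lay above that share, GATA (4.94% and 4.40%) and forkhead sites (3.16% and 3.13%) below it. With the letters of a motif reversed, as a control for base composition chosen after the data were seen that gave no value for SP and KLF or REST sites, the NRF1 string was at 67.3% and 65.0%, below the motif itself, and the MyoD-type string at 21.0% and 22.6%, not below its motif. Reversal does not keep CpG: the MyoD-type string holds CpG that its motif lacks. It had 195 and 230 instances against 10445 and 16237, so it cannot decide whether composition sets the share of the E-box. The exact 95% intervals for NRF1 were 79.4% to 84.5% (motif) and 61.3% to 72.9% (reversed) in replicate 1, and 78.6% to 83.5% and 59.7% to 70.1% in replicate 2. The reversed strings of GATA (4.60% and 4.21%) and forkhead sites (5.21% and 4.85%) lay below the share of peak bases, as their motifs did.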

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

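Alternatives chosen after the data were seen were the single TSS per gene, the CpG-matched gene lists with 1 library, the motif background matched on GC and CpG, and the motifs with reversed letters; the others were fixed before the data were examined. Of 1438 alternative values over 204 results, 1028 kept direction and side of the threshold or moved by less than their spread, 81 lost a call, 42 gained one, 212 moved and 75 changed direction. The 1028 include 100 promoter percentiles without replicate 1 and 100 without replicate 2 that were kept by construction. Leaving out 1 of 2 libraries moves their mean by no more than their standard deviation. Hotspot overlap by 1 bp and footprint overlap by 50% of both were counted as moved by rule, as other measures. The cause was not tested unless stated. Read depth is unknown, so its effect on missing calls was not measured. The upper 50% of footprints by value was not run, since the deposited value is 0.01 throughout. No paired analysis was possible because there is only 1 group. Promoter percentiles of the 100 genes taken by rule moved for 7 in the longer list of the second alignment, for 68 in its shorter list and for 75 in the upper 50% by value.

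In the longer list of the second alignment, 80.5% of replicate 1 and 48.1% of replicate 2 peaks were shared. The shorter list gave 84.3% and 49.1% and the upper 50% by value 91.8% and 56.0%. Equal numbers of peaks gave 69.6% and 68.5%, and a reciprocal overlap of 50% gave 66.2% and 40.4%. Hotspots shared 52.1% of bases in the upper 50% by value, and 82.2% of replicate 1 and 46.9% of replicate 2 hotspots overlapped by 1 bp. The Spearman correlation was 0.932 in shared regions and 0.445 from the false discovery rates over all regions. In the latter, a region without a base under 0.05 in a library took the lowest rank there. Footprints that overlapped by 50% of both made up 32.3% and 21.6%. The X share was 2.44% and 1.963% in the shorter list and 1.52% and 1.80% in the upper 50%, where the Y share was 0.0249% and 0.0188%.

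The promoter share of shared regions was 48.0% in the upper 50%, 46.8% in the shorter list, 30.2% with a window of 500 bp and 47.5% with 2500 bp. In the same order, introns held 23.1%, 23.2%, 32.5% and 23.0%, and intergenic sequence 24.7%, 26.0%, 31.2% and 26.9%. Exons held 3.97% in the shorter list and 6.12% and 2.70% with the 2 windows. Without 1 replicate, promoters held 25.9% to 35.1%, exons 4.37% to 4.91%, introns 29.2% to 33.2% and intergenic sequence 31.3% to 36.0%.

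Promoter lists above other genes numbered 4 in the upper 50% by value, 0 when matched on CpG, with both libraries or either, and 7 to 11 without 1 replicate and without matching; lists below numbered 4 in both of those, and 2 to 3 when also matched. Directions changed for myogenic genes in the longer list (66.7%) and the shorter list (61.1%), for neural crest genes in the shorter list (57.1%) and with 500 bp (64.3%), for posterior Hox genes in the shorter list (62.5%), and for endothelial genes without replicate 1 (66.7% to 72.2% over the fits without 1 replicate). Over 11 alternatives, promoter calls were kept in 11 for olfactory receptor genes, in 8 for limb mesenchyme, BMP, Wnt, housekeeping, erythroid, macrophage and hepatocyte genes, in 7 for Shh genes and in 5 for limb ectoderm and retinoic acid genes. The matched tests could not keep the calls of limb mesenchyme, Shh, BMP, Wnt, retinoic acid and housekeeping genes, since all of their members already had a peak. Matched on CpG, with both libraries, lists below their expected share in place of above were FGF (93.8%), neural crest (71.4%), anterior Hox (87.0%), posterior Hox (75%, adjusted p = 0.0324, permutation test) and forelimb or hindlimb genes (90%). Their expected shares were then 96.0%, 72.5%, 89.8%, 94.9% and 90.7%, in place of 66.6% of all genes, so the changed direction lies in the background. With matching and replicate 1 alone, the same lists changed direction, and endothelial (66.7%) and erythroid genes (27.8%) lay above their expected share. With matching and replicate 2 alone, FGF (93.8%) and myogenic genes (72.2%) lay below, and endothelial (72.2%), erythroid (33.3%) and cardiomyocyte genes (68.8%) above. Over the fits without 1 replicate the range was 71.4% to 78.6% for neural crest, 87.0% to 100% for anterior Hox, 75% to 100% for posterior Hox, and 50% to 68.8% for cardiomyocyte genes.

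Lists with more genes in the top group by distal regions numbered 8 in the shorter list and 8 with 250 kb, against 14. Of 10 alternatives, calls were kept in 10 for limb mesenchyme, limb ectoderm, BMP and olfactory receptor genes, in 9 for forelimb or hindlimb genes, in 8 for Wnt and macrophage genes, and in 7 for FGF, retinoic acid and myogenic genes. They were kept in 6 for chondrogenic and neural crest genes and in 4 for Shh genes. Of 9 alternatives, posterior Hox genes kept theirs in 9 and anterior Hox genes in 8. Neuronal genes passed in either library alone (27.8% in both), and endothelial genes in replicate 1 alone and in the longer list (27.8% in both). Directions changed for pluripotency and germ cell genes in the longer list (6.25%), in the upper 50% (6.25%), with 50 kb (0%), beyond 5 kb (6.25%) and without 1 replicate (0% to 12.5%). They changed for housekeeping genes in the longer list (11.5%), the shorter list (15.4%), the upper 50% (11.5%), with 50 kb (11.5%), with 1 TSS per gene (11.5%) and without 1 replicate (3.85% to 11.5%). With 250 kb they changed for neural crest (7.14%), neuronal (5.56%) and hepatocyte genes (11.1%), and beyond 5 kb for erythroid (5.56%) and neuronal genes (5.56%). Without 1 replicate the range was 5.56% to 27.8% for endothelial and 0% to 16.7% for hepatocyte genes. Shared peaks are fewer than the peaks of 1 library by construction: without 1 replicate the Hox clusters held 79 to 130 (HoxA), 63 to 135 (HoxB), 70 to 99 (HoxC) and 76 to 146 (HoxD).

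Motifs lower at the centre numbered 2 against shuffled sequence, 2 at equal GC and CpG and 8 to 10 without 1 replicate. Against shuffled sequence the direction changed for AP-1 (0.923), posterior HOX (1.31), LIM homeodomain (3.20), PITX (1.14), TBX (0.966), forkhead (1.89), octamer (1.66), HNF1 (3), HNF4 (1.06), MEF2 (4.06), steroid receptor (1.01) and PAX motifs (0.75). At equal GC and CpG it changed for MEIS (1.39), LIM homeodomain (2.12), TBX (0.952), the second SOX motif (1.22), forkhead (1.34), octamer (1.27), MEF2 (1.57) and steroid receptor motifs (1.02). The steroid receptor motif also changed in the longer list (1.13), the shorter list (1.12), with the flank at 1000 bp (1.12), with 50 bp (1.04) and without 1 replicate (1.117 to 1.121). Others were the second SOX motif in the longer list (1.02), TBX in the shorter list (0.847) and upper 50% (0.884), AP-1 in the upper 50% (0.993), HNF4 with the flank at 1000 bp (1.06), with 50 bp (1.02) and without 1 replicate (0.707 to 1.07), and HOX-PBX without 1 replicate (0.899 to 1.35). With reversed letters, 3 strings lay over 1.5-fold in footprints of both libraries, against 9 motifs: NRF1, the MyoD-type E-box and the retinoic acid receptor string, the last with 3 and 6 instances and not among the 9. SP and KLF and REST motifs, which are among the 9, had no value with reversed letters, so 3 and 9 do not compare like sets.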

Other observations

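The tests of repeat sequence and of the number of distal regions per gene were fixed before their results were seen; the other tests below were chosen after. The design holds 1 group, so no biological explanation from the design was tested; the share of mesenchyme weighed below is a difference in tissue composition between libraries.

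Promoter and distal regions shared by both libraries held several motifs at different shares. NRF1 sites were in 2.54% of promoter centres and 0.204% of distal centres, ETS sites in 1.94% and 0.193%, SP and KLF sites in 11.96% and 2.19%, and NF-Y sites in 7.07% and 2.06%. CTCF sites were in 2.10% of promoter centres and 9.30% of distal centres, REST sites in 0.233% and 0.433%, and GATA sites in 0.474% and 0.914%. Promoter centres had 63.6% GC and distal centres 53.5%, and the differences were not tested.

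Replicate 2 held 42177 peaks with values below 55 (24.6% of its peaks), of which 2.20% overlapped a replicate 1 peak and 6.75% lay at promoters, against 32.1% of its other peaks. The limit of 55 was set at the trough of this library's own distribution of values. Placement by chance along whole chromosomes is argued against, since the highest of 100 shifts gave 1.33%. The shifts do not keep peaks within peak-dense stretches, so chance placement inside such stretches was not tested. Repeat sequence may contribute, as repeat-masked bases made up 23.2% of distal low-value peaks and 10.7% of the others, a difference of 12.5 percentage points. The nearest peak of a low-value peak was itself low-value in 86.8% of cases, 62.2 percentage points above their share of peaks. A calling threshold that varies along the genome would give such a share. It cannot be decided from this, since the nearest peak lay a median of 250 bp away and such neighbours may share local signal under any threshold. Neither test excludes the other. These traits were not particular to replicate 2. Replicate 1 held 5116 peaks below its own trough of 35, of which 9.25% overlapped a replicate 2 peak and 6.43% lay at promoters. Repeat-masked bases made up 25.5% of the distal ones against 9.54% of its others, and the nearest peak was low-value in 82.2%. Of the low-value replicate 2 peaks, 54.4% overlapped the shorter list of the second alignment, against 58.9% of its other peaks.

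In distal regions near some gene lists, the ratio of replicate 2 to replicate 1 values stood apart from random lists. After the trend with value was removed, 8 of 22 lists lay in the outer 2.5% on either side. After the trend with GC content was removed as well, 7 did, so GC content is argued against as the whole source. These were Wnt (percentile 0.02), endothelial (0.38), limb mesenchyme (0.49), Shh (0.61), anterior Hox (0.9), BMP (1.2) and neuronal genes (98.94). In the same order, the median log2 ratio left after both trends was -0.116, -0.0878, -0.0367, -0.0921, -0.0527, -0.0553 and 0.186. These are small beside the interquartile range of the ratio over shared regions, 0.47 to 1.02. With random lists matched on the number of distal regions per gene, 6 lists lay in the outer 2.5%, so that number is argued against as the source for all lists: Wnt (0.01), endothelial (0.12), Shh (0.27), BMP (1.57) and neuronal genes (99.96) stayed, olfactory receptor genes entered (2.8 to 0.3), and limb mesenchyme (3.46) and anterior Hox genes (22.22) left. A lower share of mesenchyme in replicate 2 was assumed to raise the genes of every other limb cell type alike. The cell type in which a region is open is unknown, so that assumption was not tested. Under it, a lower share is argued against as the whole source, since endothelial genes lay as low as mesenchyme genes. Myogenic (30.16), ectoderm (60.99), neural crest (63.14), erythroid (77.33), macrophage (84.93) and neuronal genes lay higher. With matching, myogenic genes lay at 62.66, ectoderm at 89.84, neural crest at 80.63, erythroid at 83.95 and macrophage genes at 96.18, so the argument then rests on endothelial genes alone, and a change in single cell types stays open.

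Strong replicate 2 regions more often had no base under a false discovery rate of 0.05 in replicate 1 where peaks are crowded, with the Hox clusters left out of the count. Among the most crowded 10% of strong regions, with more than 20 other replicate 2 regions within 25 kb, 451 of 4999 (9.02%) had none, 4.41 times (95% bootstrap interval 3.65 to 5.21) the share at equal value. Of the other strong regions 1.60% had none, so such regions were not confined to crowded places. A difference in depth that acts through value alone is argued against, as is GC content, the latter by a ratio of 4.26 (3.54 to 5.01) at equal value and GC. A caller that judges each site against its surroundings may act here and cannot be told apart from other sources: of 2513 crowded replicate 1 regions, 1 had no such base in replicate 2, a ratio of 2.22 with an interval of 0 to 7.55, which is too few to decide. In the Hox clusters and within 25 kb of them, 36.8% of strong replicate 2 regions had no such base in replicate 1. In the other direction it was 0 of 126.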
